A study of Homo sapiens with 12 samples.

How the data were processed

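Gene expression was measured by RNA-seq in LC-2/ad and TPC-1 cells, each as untreated parent cells and after 48 h in 100 nM selpercatinib, with 3 libraries in each of the 4 groups. Per the labels' protocols, total RNA was extracted with a column kit and libraries followed Illumina's protocols. LC-2/ad cells grew in a mixture of RPMI-1640 and F-12 and TPC-1 cells in RPMI-1640, both with serum. The labels give the parent cells' treatment as none and do not say whether they received the drug's solvent. The deposited values were TPM per gene and library, in 1 table per line. Each column summed to 1000000 within rounding, so the authors' TPM are scaled within a library and no scaling between libraries was seen. The submitters' processing notes name bcl2fastq 2.20.0, Salmon and the GRCh38 build without their roles. The annotation, the way transcripts were summed to genes and any filter are not stated. TPM keep no count of reads, so the depth is unknown and no interval for counting error is given. Precision is described by the spread between libraries.

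Each table held the same 37247 Ensembl gene identifiers, of which 34436 (92.5%) had a gene symbol and 34620 were in GENCODE 29, whose GRCh38 coordinates are those printed. Groups were taken from the sample labels. Within each line log2(TPM + 1) was compared between treated and parent libraries with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), for genes with a mean TPM of at least 1 over the 6 libraries. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A log2 fold change is treated minus parent, and its SE is limma's moderated one. The lines were compared by the difference of their log2 fold changes (TPC-1 minus LC-2/ad) in a fit of all 12 libraries, for genes with a mean TPM of at least 1 in each line, so that a constant offset between the tables cancels. Shared changes were counted from the fits of each line and set beside the number that independent lists of the same sizes would share, n1 times n2 over the number of genes tested. No libraries are shared between the lines.

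Gene lists (29) for signalling, cell cycle, metabolism, stress, immune, lineage, mitochondrial and contaminating cell transcripts were fixed, as were the tests, the thresholds, the alternatives and the rule for naming genes, before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, with adjustment over the lists, and again with an estimated correlation. The self-contained test fry asks whether a list's genes move on balance in 1 direction and compares them with no other genes. Members were counted by the limma test adjusted over all genes tested, and again adjusted over the list alone.

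Genes were named by rule: in each line the 10 with the largest rise and the 10 with the largest fall among called genes with a mean TPM of at least 5 in a group and treated values all on 1 side of the parent values, 17 genes of the pathways in question, up to 4 members per list with the largest change, and, for the comparison of the lines, the 5 shared changes and the 5 differences per direction with the largest size. Genes outside the rule are named in the closing part as chosen after their values were seen. Some genes that the rule would name are not reported here. Pseudogenes, overlapping paralogs, genes of the MHC region and genes with near-identical copies are given as uncertain, since the tables do not show how reads were shared.

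Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a mean TPM of at least 5, median-of-ratios scaling, removal of mitochondrial genes, no variance trend, the replicate number as a block, and leaving out each library in turn. Protein-coding genes alone and a spread weight per line were added after the data were seen. The tests were tried on simulated log2 values built from the real parent group means and spread, with normal noise independent between genes. In each line 224 genes were changed by known amounts (4 sizes in 50 genes each and a list of 24), and 200 for the difference between the lines. Apart from the list, changed genes were drawn from those at about 5 TPM or more in parent cells. The shares below therefore do not cover lower genes, nor data where most genes change. For LC-2/ad (13612 genes) changes of 0.25, 0.5, 1 and 2 on the log2 scale were recovered in 20%, 70%, 84% and 98% of 50 genes each, and 6% of the calls were unchanged genes. For TPC-1 (12606 genes) the shares were 10%, 48%, 90% and 100%, with 3.9% of calls unchanged. For the difference between the lines (11729 genes) changes of 1 were recovered in 92% of 200 genes, with 6.6% of calls unchanged. Tables were read and figures drawn with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No deposited column was left out.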

Results

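RNA was sequenced from 2 human cancer cell lines that the series title calls RET-aberrant, LC-2/ad from a lung adenocarcinoma and TPC-1 from a papillary thyroid carcinoma, both known to carry a RET gene fusion. Selpercatinib is an inhibitor of the RET receptor tyrosine kinase. Each line was measured as parent cells without treatment and after 48 h in 100 nM selpercatinib, with 3 libraries per group and 12 in all. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between libraries, which may be technical. The values were TPM, which keep no record of sequencing depth, so the depth of each library is unknown. Between 13713 and 14336 genes had a TPM of at least 1 in each LC-2/ad library, and between 12554 and 12967 in each TPC-1 library. Transcripts of mitochondrial DNA made up 9.77% ± 0.05 (SD, n = 3) of the TPM in LC-2/ad parent cells and 14.56% ± 0.49 after treatment, against 6.98% ± 0.58 and 6.32% ± 0.5 in TPC-1. The main axis of variation separated treated from parent libraries in each line and held 68.8% of the variance in LC-2/ad and 38.4% in TPC-1, where parent library 1 lay at -4.9 and the other parent libraries at -23.3 and -17.7.

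The LC-2/ad comparison asked which transcripts differ when RET is inhibited in a RET-aberrant lung cancer line. Transcripts that follow ERK signalling were lower in the treated cells. DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271, GRCh38), a phosphatase that ERK signalling induces and that in turn inactivates ERK, fell from 160 ± 2.83 to 12.9 ± 1.84 TPM (mean ± SD, n = 3), a log2 fold change of -3.54 ± 0.09 (SE). MKI67, a marker of proliferating cells, fell from 59.1 ± 3.8 to 17 ± 0.21 TPM, and all 28 genes tested for DNA replication fell. ERBB2, a receptor tyrosine kinase of the EGFR family, rose from 186 ± 9.17 to 346 ± 2.74 TPM, and CYP1A1, an enzyme of xenobiotic metabolism, rose from 52.4 ± 3.03 to 561 ± 11.9 TPM. IGFBP5, a binding protein of insulin-like growth factors, rose from 7.92 ± 0.393 to 59 ± 1.64 TPM.

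Gene lists were fixed by pathway and described by the members that passed a limma test adjusted over all genes, and the count adjusted over the list alone was the same in LC-2/ad unless it is given. Of 19 genes that ERK signalling induces, 18 fell. Examples are the transcription factors ETV4 (log2 fold change -2.94 ± 0.11), ETV5 (-2.55 ± 0.09) and ETV1 (-1.73 ± 0.22) and the ERK pathway inhibitor SPRY4 (-1.47 ± 0.10). The list had a camera adjusted p of 2.43e-11. CCND1, the cyclin that drives entry into S phase, fell from 222 ± 6.15 to 102 ± 3.02 TPM. MYC, a transcription factor of cell growth, fell from 182 ± 3.96 to 116 ± 3.95 TPM. All 28 S phase genes fell, with RRM2 (-2.04 ± 0.06), TK1 (-1.83 ± 0.04) and CDC6 (-1.69 ± 0.05) as examples (camera adjusted p = 3.29e-18). All 27 mitotic genes of the G2/M list fell, including PLK1 (-2.10 ± 0.06), DLGAP5 (-2.09 ± 0.06) and TOP2A (-1.98 ± 0.05), with a camera adjusted p of 1.61e-20. Among 15 CDK inhibitor and quiescence genes 7 rose and 5 fell, and the list was not called (adjusted p = 0.725). The CDK inhibitor CDKN1C rose by 1.48 ± 0.31 and CDKN1B by 0.30 ± 0.07, while CDKN2D (-1.02 ± 0.12) and CDKN2C (-0.99 ± 0.09) fell.

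Genes of growth and metabolism were mostly lower in treated LC-2/ad cells. Of 24 ribosome biogenesis genes 23 fell, with NOP56 at -1.08 ± 0.07 and ODC1 at -0.93 ± 0.05 (camera adjusted p = 2.29e-11). In the cholesterol synthesis list 17 of 24 genes fell and 1 rose, INSIG1 (-1.26 ± 0.06) being an example (adjusted p = 8.7e-07). Lipogenic genes fell in 11 of 13 cases and rose in 2, with the desaturase SCD at -2.40 ± 0.04 and FADS2 at -1.86 ± 0.09 (adjusted p = 4.9e-05, and adjusted p = 0.0589 with an estimated correlation). For glycolysis 15 of 20 genes fell and 1 rose (adjusted p = 5.36e-07, and adjusted p = 0.0589 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 2303 ± 112 to 863 ± 13.8 TPM. Amino acid and stress genes of the ATF4 list fell in 15 of 22 cases and rose in 2, with GDF15 at -2.54 ± 0.06 and STC2 at -1.15 ± 0.05 (adjusted p = 4.23e-05). All 13 protein-coding transcripts of mitochondrial DNA rose, such as MT-ND1 (0.77 ± 0.04) and MT-CO3 (0.75 ± 0.02). They had a camera adjusted p of 5.36e-07 and an adjusted p = 0.155 with an estimated correlation. Nuclear genes of the respiratory chain moved the other way, with 17 of 24 lower (18 adjusted over the list alone, adjusted p = 9.63e-07). CYCS changed by -0.95 ± 0.05 and SDHB by -0.46 ± 0.04. Of 11 cytosolic and mitochondrial chaperones 10 fell (11 adjusted over the list alone), including HSPH1 at -0.95 ± 0.05 and HSPD1 at -0.88 ± 0.03 (adjusted p = 9.63e-07, and adjusted p = 0.155 with an estimated correlation).

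Several lists rose in LC-2/ad. Of 35 interferon-stimulated genes 27 rose and 4 fell (5 fell adjusted over the list alone). Risers were XAF1 (1.87 ± 0.10), IFI27 (1.75 ± 0.12), IRF9 (1.72 ± 0.10) and IFIT1 (1.54 ± 0.13). The list had an adjusted p of 1.09e-05 and an adjusted p = 0.179 with an estimated correlation. Antigen presentation genes rose in 8 of 14 cases (adjusted p = 0.000536, and adjusted p = 0.0589 with an estimated correlation). CD74, the invariant chain of MHC class II, rose from 63.3 ± 2.07 to 126 ± 1.49 TPM. Values of genes in the MHC region on chromosome 6 (GRCh38), such as HLA-DRA (1.04 ± 0.09) and HLA-E (0.92 ± 0.04), are uncertain. In that region 21 of 141 protein-coding genes were at 0 in all 12 libraries (14.9%, against 8.5% elsewhere). FOXO targets rose in 15 of 20 cases (17 adjusted over the list alone, adjusted p = 0.000323, and adjusted p = 0.235 with an estimated correlation). PIK3IP1, an inhibitor of PI3K, rose by 2.12 ± 0.09 and the death ligand TNFSF10 by 1.19 ± 0.08. YAP/TAZ targets rose in 16 of 22 cases and fell in 4 (adjusted p = 0.00791, and adjusted p = 0.188 with an estimated correlation). TGFB2 rose by 1.39 ± 0.08, ANKRD1 by 1.33 ± 0.07, CCN2 by 0.91 ± 0.08 and CCN1 by 0.63 ± 0.04. YAP1 itself, the coactivator of these genes, rose by 0.19 ± 0.04. Cytokines and NF-kB targets rose in 14 of 19 cases and fell in 2 (adjusted p = 0.00446, and adjusted p = 0.235 with an estimated correlation). CXCL3 rose by 1.62 ± 0.14 and IL32 by 1.49 ± 0.08, while IL6 fell by 0.51 ± 0.11. Mesenchymal genes rose in 11 of 17 cases and fell in 2 (adjusted p = 0.00678, and adjusted p = 0.179 with an estimated correlation). COL5A1 (1.62 ± 0.08) rose and TNC (-1.51 ± 0.10) fell. Lysosome and autophagy genes rose in 15 of 28 cases (16 adjusted over the list alone) and fell in 4 (adjusted p = 0.00861, and adjusted p = 0.188 with an estimated correlation). WIPI1 rose by 1.40 ± 0.08 and GABARAPL1 by 1.32 ± 0.12. Of 7 tested thyroid lineage genes 6 rose and 1 fell, with FOXE1 at 1.56 ± 0.07 and DIO2 at 1.47 ± 0.19 (adjusted p = 0.0132, and adjusted p = 0.155 with an estimated correlation).

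The remaining LC-2/ad lists were not called and held members that moved both ways or in part. Of 22 receptor tyrosine kinases 9 rose and 5 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.332). MET, the receptor of hepatocyte growth factor, fell from 383 ± 13.9 to 164 ± 10.4 TPM. ERBB3, the partner of ERBB2, rose from 65 ± 8.62 to 109 ± 4.71 TPM. RET, the drug's target (ENSG00000165731, chromosome 10, 43077027 to 43130351), rose from 16 ± 0.422 to 21.4 ± 0.683 TPM, a gene-level value that does not separate a fusion transcript. EGFR had a log2 fold change of -0.15 ± 0.06 and an adjusted p of 0.0747, against 0.0192 after median-of-ratios scaling and 0.0307 without treated library 2. Growth factor ligands rose in 6 of 15 cases and fell in 3 (adjusted p = 0.919). The EGFR ligands EREG (-2.48 ± 0.07) and AREG (-2.38 ± 0.05) fell while GAS6, a ligand of the TAM receptor kinases, rose by 1.29 ± 0.09. In the BCL2 family 5 of 13 genes rose (6 adjusted over the list alone) and 3 fell (adjusted p = 0.724), with the proapoptotic BMF rising from 38.7 ± 1.37 to 129 ± 5.42 TPM. BCL2L11, which encodes BIM, rose by 0.52 ± 0.15, and its adjusted p was 0.0587, 0.0564 and 0.0558 without parent library 2 and treated libraries 1 and 2, and 0.0522 without the filter. Epithelial genes rose in 12 of 24 cases and fell in 6 (13 and 8 adjusted over the list alone, camera adjusted p = 0.466), with OVOL2 at 0.71 ± 0.08 and KRT18 at -0.69 ± 0.02. Lung lineage genes rose in 10 of 16 cases and fell in 3 (adjusted p = 0.0719, but 0.0465 without parent library 2), with HOPX at 1.87 ± 0.10 and AQP3 at -1.20 ± 0.04. Hypoxia targets rose in 8 of 14 cases (adjusted p = 0.107, but 0.0364 at a mean TPM of at least 5), p53 targets rose in 7 and fell in 11 of 21 (adjusted p = 0.148), and genes of the unfolded protein response rose in 7 and fell in 7 of 19 (adjusted p = 0.725). Examples of these lists were ADM at 0.81 ± 0.10, TP53INP1 at 2.02 ± 0.07 and HERPUD1 at 0.75 ± 0.10. Of the markers of blood, endothelial cells and fibroblasts 3 were high enough to test, and LUM rose from 0.495 ± 0.0304 to 2.12 ± 0.591 TPM and CDH5 from 2.07 ± 0.176 to 3.63 ± 0.446 TPM.

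Among the single genes with the largest rises in LC-2/ad, VTCN1, an immune checkpoint ligand, went from 11.2 ± 0.509 to 74.7 ± 5.4 TPM. HPX, which encodes hemopexin, rose by 2.60 ± 0.43. CHIA, a chitinase, rose from 0.0408 ± 0.0706 to 5.9 ± 0.702 TPM, ATP13A4 rose by 2.54 ± 0.21 and CLIC3 by 2.46 ± 0.07. The values of APOBEC3A (3.43 ± 0.19), whose annotated span overlaps that of a paralog, and of the pseudogenes CYP2B7P (2.67 ± 0.04) and CYP2T1P (2.58 ± 0.07) are uncertain because reads can be shared with similar genes. The largest falls included FOXJ1, the transcription factor of ciliated cells, at -2.94 ± 0.15. The pseudogenes SRP9P1 and RPL39P16 were listed at 0 in all treated LC-2/ad libraries, against 27.4, 28.7 and 10.0 TPM and 13.6, 5.23 and 7.36 TPM in the parent libraries. Both were also listed at 0 in some libraries of TPC-1 parent cells, which had no drug. RPP21, in the MHC region, was at 7.57, 6.39 and 6.02 TPM in the parent libraries and at 0.0651, 1.39 and 0 TPM after treatment.

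By limma with Benjamini-Hochberg adjustment 7770 of 14118 tested genes differed in LC-2/ad (55%), of which 4319 rose and 3451 fell. Of these 1115 changed by at least 1 on the log2 scale (648 up, 467 down). Camera called 19 of 28 lists, 9 up and 10 down. With an estimated correlation 7 calls held, all of them falls: ERK feedback, S phase, G2/M, ribosome biogenesis, cholesterol synthesis, ATF4 response and nuclear respiratory chain. Which direction prevailed among changed genes depended on scaling, with 3757 up and 3980 down after median-of-ratios scaling and 5216 up and 2833 down after removal of mitochondrial genes.

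**Figure D1:**
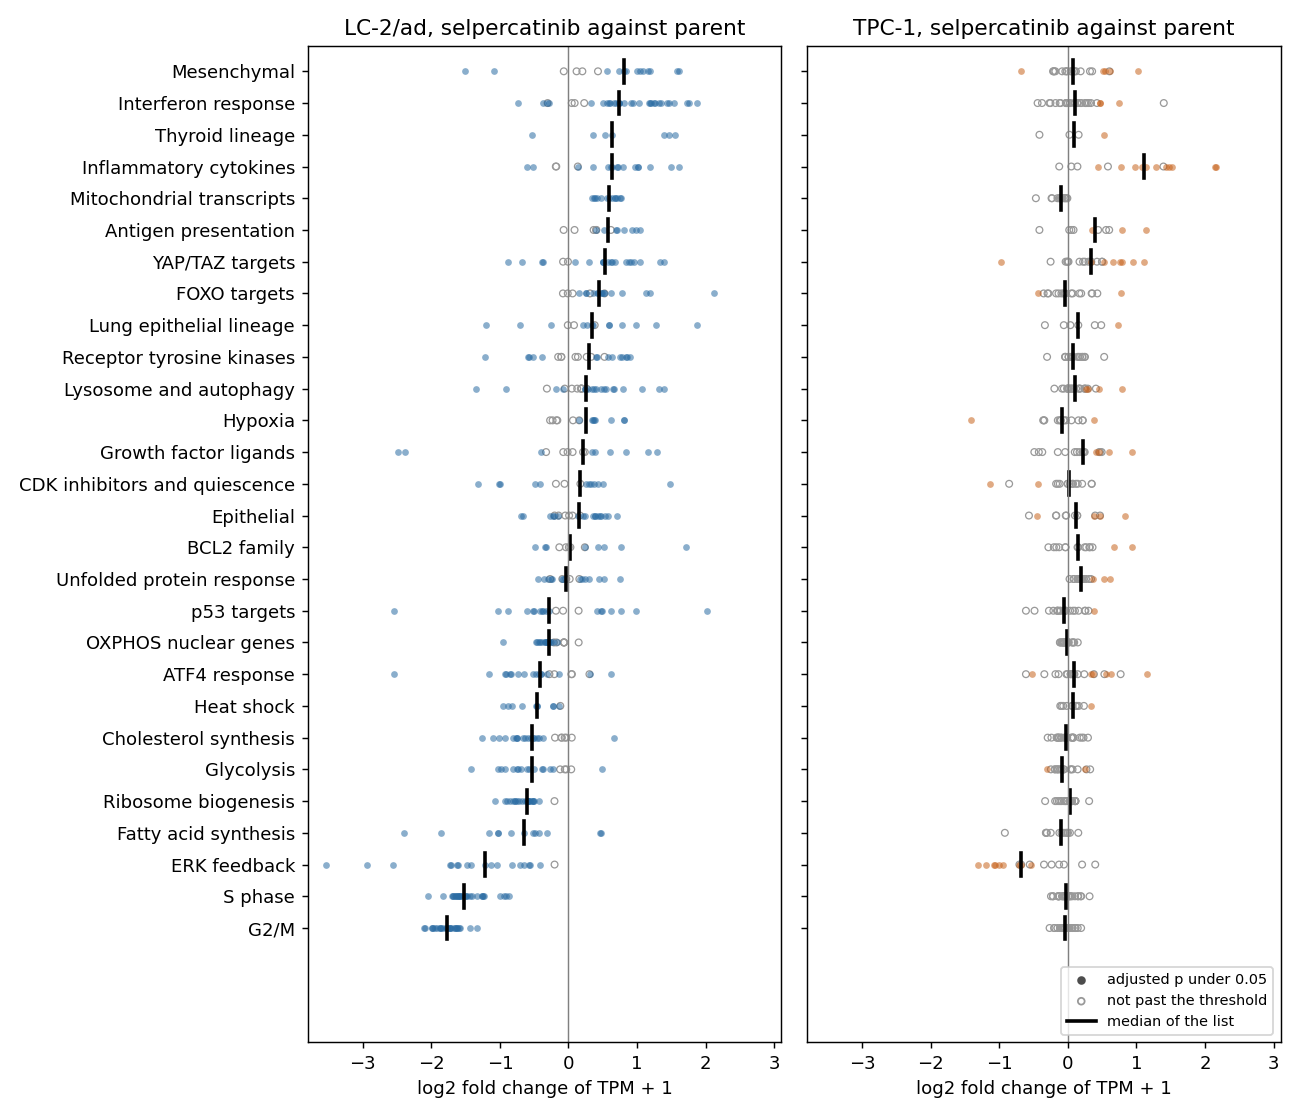
Log2 fold changes of TPM + 1 (selpercatinib against parent, horizontal axis) of each tested member of the 28 gene lists (vertical axis) in LC-2/ad (left) and TPC-1 (right), n = 3 libraries per group. Filled dots passed the limma test at an adjusted p under 0.05, open dots did not, and black bars are list medians, which for the G2/M list lie at -1.77 in LC-2/ad and -0.05 in TPC-1.

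The TPC-1 comparison asked the same of a RET-aberrant thyroid cancer line. Of 16 cytokines and other NF-kB targets 11 were higher in treated TPC-1 cells. EDN2 (ENSG00000127129, chromosome 1, 41478775 to 41484673), which encodes the vasoactive peptide endothelin 2, rose from 10.7 ± 1.40 to 90.5 ± 12 TPM (mean ± SD, n = 3), a log2 fold change of 2.96 ± 0.12 (SE). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002), an inflammatory cytokine, rose from 6.68 ± 0.613 to 33.5 ± 5.12 TPM, and CCL2, a chemokine that attracts monocytes, from 13.3 ± 0.96 to 62.3 ± 5.89 TPM. DUSP6 fell from 12.7 ± 1.18 to 5.91 ± 1.41 TPM, and EGR1, an immediate early transcription factor, from 12 ± 0.885 to 4.26 ± 0.249 TPM. No S phase or G2/M gene passed the limma test (4 and 4 at an unadjusted p under 0.05), and MKI67 stood at 90.9 ± 1.59 TPM in parent and 87.9 ± 6.94 TPM in treated cells.

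These inflammatory genes rose in 11 of 16 cases (13 adjusted over the list alone), including NFKBIA, the inhibitor of NF-kB that NF-kB induces, at 1.52 ± 0.11 and BIRC3 at 1.47 ± 0.14. The camera adjusted p was 4.03e-12, and adjusted p = 0.317 with an estimated correlation. Of 18 ERK feedback genes 9 fell (13 fell and 1 rose adjusted over the list alone), with ETV4 at -1.19 ± 0.15 and DUSP6 at -1.0 ± 0.16. That list had a camera adjusted p of 6.38e-12, and adjusted p = 0.317 with an estimated correlation. DUSP6 lost its call without the filter on low values (adjusted p = 0.0641). SPRY4 fell by 1.08 ± 0.22 and ETV1 by 1.06 ± 0.19, with an adjusted p of up to 0.0865 (SPRY4, without parent library 2) and 0.0618 (ETV1, without parent library 3) over the alternatives. The SPRY4 call ended in 5 and the ETV1 call in 3 of the 6 fits that leave out 1 library, and both without the filter (0.0838 and 0.0612). CCND1 (-0.35 ± 0.12, adjusted p = 0.143), MYC (-0.06 ± 0.10, adjusted p = 0.801) and ETV5 (-0.68 ± 0.20, adjusted p = 0.0883) did not pass, though CCND1 did without treated library 2 (-0.49, adjusted p = 0.0229). YAP/TAZ targets rose in 7 of 21 cases and fell in 1 (13 and 2 adjusted over the list alone). IGFBP3 rose from 474 ± 31.1 to 1030 ± 139 TPM, CCN1 from 428 ± 31.3 to 729 ± 45.4 TPM and AMOTL2 by 0.79 ± 0.07, while NT5E fell by 0.98 ± 0.07. That list had a camera adjusted p of 0.000116, and adjusted p = 0.603 with an estimated correlation. CCN2 (0.25 ± 0.09, adjusted p = 0.154) and YAP1 (-0.05 ± 0.08, adjusted p = 0.791) did not pass. For the unfolded protein response 3 of 19 genes rose (9 adjusted over the list alone), with XBP1 at 0.52 ± 0.06 and HYOU1 at 0.37 ± 0.06 (camera adjusted p = 5.22e-06, and adjusted p = 0.603 with an estimated correlation). Antigen presentation genes rose in 3 of 10 cases (4 adjusted over the list alone), with CD74 going from 31.5 ± 1.38 to 55.4 ± 3.09 TPM (adjusted p = 0.0223, and adjusted p = 0.603 with an estimated correlation).

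Cell cycle and mitochondrial lists held no called member in TPC-1. By limma 0 of 28 S phase genes passed, with 4 below an unadjusted p of 0.05, all lower. The list adjusted p was 0.0589, against 0.0434 without parent library 2, 0.0453 without treated library 2, 0.0427 without the filter, 0.0467 with the mitochondrial genes removed and 0.0223 after median-of-ratios scaling (median -0.08). It ranged up to 0.603, the value with an estimated correlation. Of 27 G2/M genes 0 passed by limma, with 3 lower and 1 higher at an unadjusted p under 0.05 and a median log2 fold change of -0.05. After median-of-ratios scaling DLGAP5 of that list passed (-0.32, adjusted p = 0.0385). Camera gave the G2/M list an adjusted p of 0.0435, against 0.116 without parent library 1, 0.42 without treated library 3 and 0.0534 without a variance trend, and adjusted p = 0.606 with an estimated correlation. The self-contained test fry gave adjusted p-values of 0.414 for S phase and 0.659 for G2/M. Of the 13 mitochondrial transcripts 0 passed by limma (2 lower at an unadjusted p under 0.05), with a median of -0.10. Their list adjusted p of 0.001 was 0.0515 without parent library 3, and adjusted p = 0.603 with an estimated correlation. Fatty acid synthesis genes gave 0 of 13 by limma (3 lower at an unadjusted p under 0.05) with SCD at -0.92 ± 0.24 (adjusted p = 0.0653). SCD passed at a mean TPM of at least 5 (0.0366), with protein-coding genes alone (0.0374) and without treated library 3 (-1.24, 0.00191). The fatty acid synthesis adjusted p of 0.018 was 0.0515 without parent library 3, 0.062 without treated library 1 and 0.0682 without treated library 2, and adjusted p = 0.603 with an estimated correlation. In glycolysis 1 gene rose and 1 fell of 19 (3 and 5 adjusted over the list alone), PFKP at 0.26 ± 0.06 and LDHA at -0.30 ± 0.07. Each call ended in 5 of the 6 fits that leave out 1 library, with an adjusted p of up to 0.143 for PFKP (without parent library 3) and 0.167 for LDHA (without parent library 2). They also ended without the filter (0.0989 and 0.219), after median-of-ratios scaling (0.0528 and 0.0874) and without a variance trend (0.141 and 0.157). The glycolysis adjusted p of 0.023 was 0.0518, 0.0546 and 0.227 without parent library 1, parent library 2 and treated library 1, 0.0678 after median-of-ratios scaling, 0.0541 without the filter, 0.0534 without a variance trend, and adjusted p = 0.603 with an estimated correlation. Lysosome genes rose in 4 of 26 cases (7 adjusted over the list alone), with GABARAPL1 at 0.80 ± 0.14 (adjusted p = 0.0575 without treated library 1 and 0.0717 without the filter). Their list adjusted p of 0.0345 was 0.062 and 0.0929 without treated libraries 1 and 2, 0.0678 after median-of-ratios scaling, 0.0719 without a variance trend, and adjusted p = 0.603 with an estimated correlation.

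Lists without a call in TPC-1 were growth factor ligands (4 of 18 rose, 6 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.113) and ATF4 response (5 rose and 1 fell of 23, 7 and 3 adjusted over the list alone, 0.168). So were mesenchymal genes (4 rose and 1 fell of 22, 7 and 1 adjusted over the list alone, 0.144) and interferon response (3 of 29 rose, as adjusted over the list alone, 0.407). Examples were PDGFB, a platelet-derived growth factor chain, at 0.93 ± 0.08 and STC2 at 1.15 ± 0.12. Epithelial genes rose in 3 and fell in 1 of 14 cases (4 and 2 adjusted over the list alone, 0.407), with the transcription factor ELF3 rising by 0.83 ± 0.10 and KRT18 falling by 0.44 ± 0.06. The BCL2 family rose in 2 of 15 cases (3 rose and 1 fell adjusted over the list alone, 0.407). BCL2A1 went from 5.89 ± 0.71 to 12.1 ± 1.24 TPM, and BCL2L11 did not pass (-0.28 ± 0.17, adjusted p = 0.371). Counts adjusted over the list alone equalled the others for FOXO targets (1 rose and 1 fell of 19, 0.557), CDK inhibitors (2 of 16 fell, 0.168) and p53 targets (1 of 21 rose, 0.144). CITED2 rose by 0.77 ± 0.08 and HES1 fell by 1.13 ± 0.16, and CDKN1B did not pass (0.03 ± 0.08, adjusted p = 0.877). Hypoxia targets rose in 1 and fell in 1 of 16 cases (1 and 3 adjusted over the list alone, 0.0673), with ANGPTL4 at -1.41 ± 0.18. The hypoxia adjusted p was 0.0278 without parent library 3 and 0.0108 without treated library 3. Of 11 chaperones HSPB1 rose by 0.34 ± 0.04 (2 rose adjusted over the list alone, 0.378), a call that ended without a variance trend (0.0524). Of 7 lung lineage genes LPCAT1 rose by 0.73 ± 0.10 (2 adjusted over the list alone, 0.407), which ended without the filter (0.0507). By limma 0 genes passed among 23 for cholesterol synthesis (3 higher and 2 lower at an unadjusted p under 0.05, list adjusted p = 0.168, and 0.0104 without treated library 3) and 24 for ribosome biogenesis (1 and 3, 0.407). The same held for 24 genes of the nuclear respiratory chain (0 and 0, 0.113, but 0.0212 after median-of-ratios scaling) and 19 receptor tyrosine kinases (1 and 1, 0.407). RET (-0.03 ± 0.10, adjusted p = 0.889), ERBB2 (0.08 ± 0.07, 0.537), ERBB3 (0.24 ± 0.15, 0.409), EGFR (0.25 ± 0.08, 0.112) and MET (-0.30 ± 0.09, 0.092) did not pass in TPC-1. MET passed with the replicate number as a block (0.0461) and after median-of-ratios scaling (-0.36, 0.0296), and EGFR without parent library 1 (0.33, 0.0369). NRG1, the ligand of ERBB3, rose from 11.7 ± 0.686 to 16.3 ± 1.78 TPM, with an adjusted p of 0.0454, a call that ended in 5 of the 6 fits that leave out 1 library (adjusted p up to 0.142, without parent library 3). Of 4 tested thyroid lineage genes PAX8 rose by 0.53 ± 0.12 (adjusted p = 0.0458, up to 0.179 without the filter), a call that ended in 5 of the 6 fits that leave out 1 library. Of 2 tested markers of other cell types ACTA2 fell by 0.42 ± 0.10 (adjusted p = 0.0414, up to 0.168 without parent library 3), a call that ended in 6 of these 6 fits. Both lists were too small for a list test.

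Further large rises in TPC-1 were those of TRAF1 (2.08 ± 0.14) and TNFRSF9 (1.68 ± 0.10), members of tumour necrosis factor signalling, TMEM40 (1.96 ± 0.10), EDN1 (1.58 ± 0.16) and IGFBP5 (1.55 ± 0.16). The 10 largest falls among called genes with a symbol, a mean TPM of at least 5 in a group and separated values were those of DHRS3, a retinaldehyde reductase, from 7.96 ± 0.867 to 1.62 ± 0.207 TPM, EMP1 (-1.65 ± 0.10), SIGLEC15 (-1.56 ± 0.16), EGR1 (-1.31), WNT7A (-1.24 ± 0.23), ETV4 (-1.19), the carbonic anhydrase CA12 (-1.17 ± 0.10), TGM2 (-1.14 ± 0.09), SOX9 (-1.09 ± 0.13) and SLCO4A1 (-1.05 ± 0.15). WNT7A had an adjusted p of 0.0161, which was 0.0635 and 0.0647 without parent libraries 2 and 3, 0.0686 and 0.0587 without treated libraries 1 and 2, 0.0584 without a variance trend and 0.108 without the filter. SLCO4A1 had 0.0502 without the filter.

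By limma 636 of 12825 tested genes differed in TPC-1 (5.0%), of which 481 rose and 155 fell (434 and 255 after median-of-ratios scaling). Of these 79 changed by at least 1 on the log2 scale (56 up, 23 down). Camera called 10 of 27 lists, 5 up and 5 down, and with an estimated correlation 0 (2 lists had an unadjusted p under 0.05), while fry called 2. The gene count was 272 without the filter on low values and 356 without a variance trend. Leaving out 1 library gave 337 without parent library 2, 292 without parent library 3, 335 without treated library 1 and 339 without treated library 2.

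**Figure D2:**
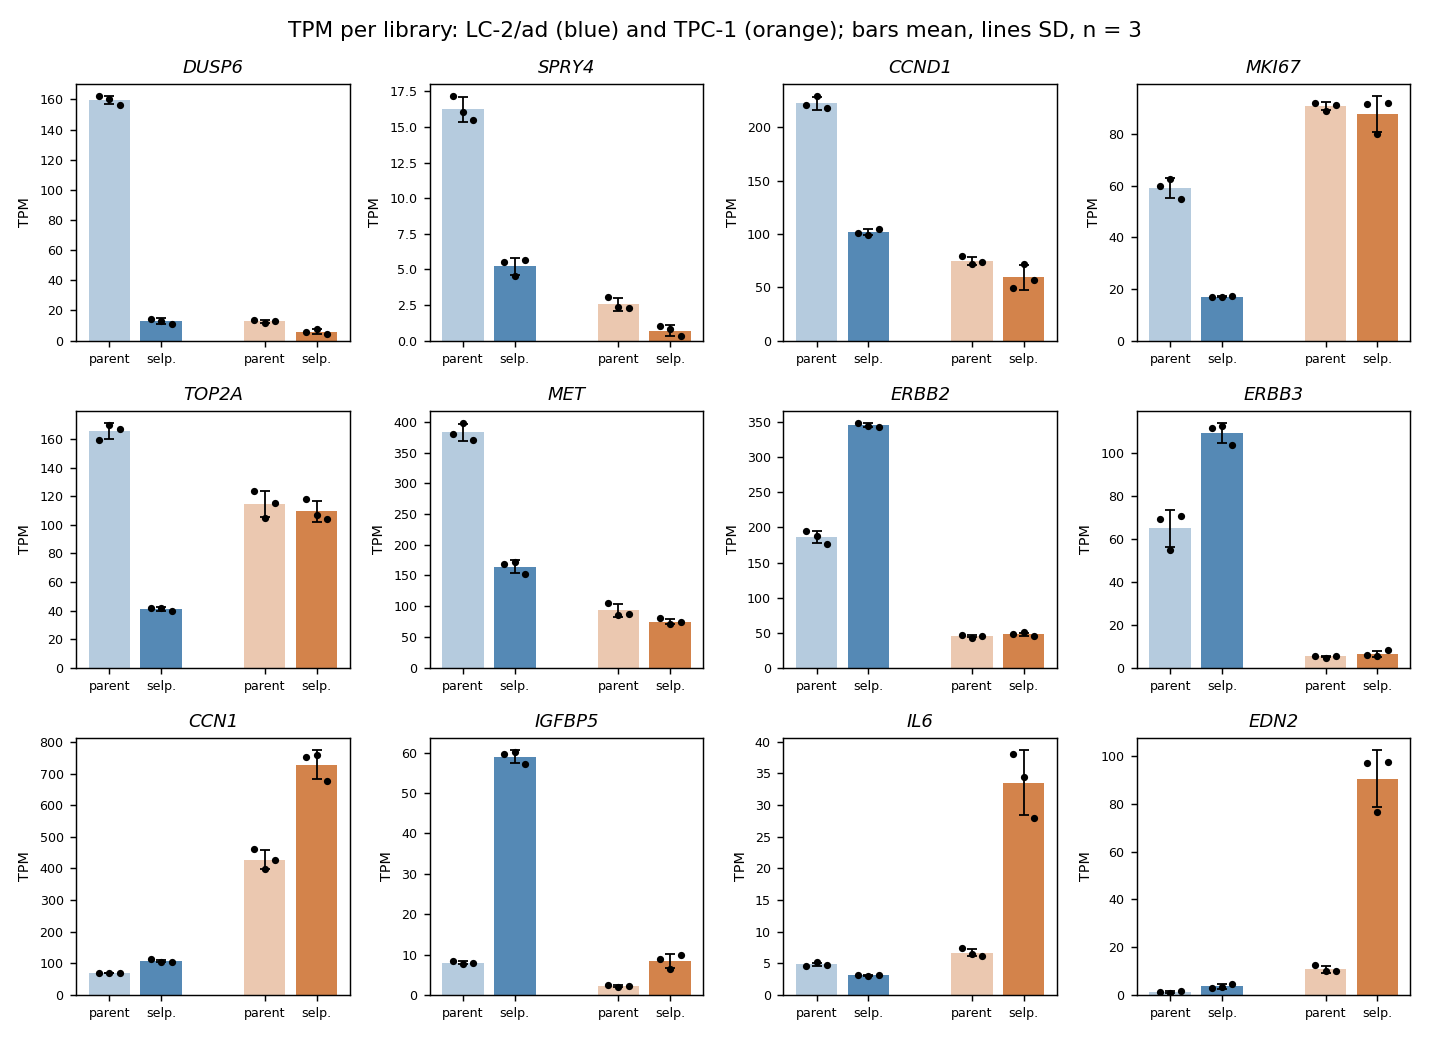
TPM (vertical axes, each from 0) of 12 genes in each library of LC-2/ad (blue) and TPC-1 (orange), parent and selpercatinib, with points for libraries, bars for means and lines for SD, n = 3. DUSP6 is lower after treatment in both lines (12.9 against 160 TPM in LC-2/ad, 5.91 against 12.7 TPM in TPC-1). IL6 is higher after treatment in TPC-1 (33.5 against 6.68 TPM) and lower in LC-2/ad (3.07 against 4.8 TPM).

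The comparison of the lines asked which responses differ between them and which run the same way. The cell cycle response differed: MKI67 fell in LC-2/ad, and the difference of log2 fold changes (TPC-1 minus LC-2/ad) was 1.69 ± 0.09 (SE, n = 3 per group). DUSP6 differed by 2.54 ± 0.19 and the EGFR ligands AREG and EREG by 2.61 ± 0.11 and 2.59 ± 0.14. IL6 rose in TPC-1 and fell in LC-2/ad, a difference of 2.67 ± 0.16. DHRS3 rose in LC-2/ad and fell in TPC-1, a difference of -2.40 ± 0.12.

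All 28 S phase and all 27 G2/M genes had a called difference, each in the direction of a higher TPC-1 log2 fold change, with PLK1 at 2.11 ± 0.09 and RRM2 at 2.00 ± 0.08. The camera adjusted p was 1.33e-21 for S phase and 5.61e-26 for G2/M. Nuclear respiratory chain genes differed in the same direction in 16 of 24 cases and in the opposite one in 1 (adjusted p = 0.000213). ERK feedback genes did so in 11 of 17 cases and in the opposite one in 0 (adjusted p = 0.00017, and adjusted p = 0.155 with an estimated correlation). Ribosome biogenesis (22 of 24, adjusted p = 1.25e-09, and adjusted p = 0.145 with an estimated correlation), glycolysis (14 of 19, 4.34e-06 and 0.149), and chaperones (10 of 11, 5.76e-07 and 0.149) also had higher TPC-1 log2 fold changes. So did the ATF4 response (13 of 22, with 1 lower, 7.96e-06 and 0.149), cholesterol synthesis (15 of 23, with 1 lower, 0.000145 and 0.149) and fatty acid synthesis (9 of 13, with 2 lower, 0.00467 and 0.233). STC2 fell in LC-2/ad and rose in TPC-1, a difference of 2.31 ± 0.15, and HSPH1 differed by 1.18 ± 0.08. Inflammatory genes were higher by this measure in 9 of 14 cases and lower in 1 (adjusted p = 0.00142, and adjusted p = 0.214 with an estimated correlation), with CCL2 at 2.01 ± 0.13. The unfolded protein response was called too (8 of 19 higher and 1 lower, adjusted p = 0.0385, and adjusted p = 0.453 with an estimated correlation). That call was lost without LC-2/ad parent library 2 (0.0503), LC-2/ad treated library 3 (0.0518) or TPC-1 parent library 2 (0.0555). It was also lost at a mean TPM of at least 5 (0.0995), with the mitochondrial genes removed (0.0987), without a variance trend (0.0551) and with the replicate number as a block (0.0502).

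Lower TPC-1 log2 fold changes were called for all 13 mitochondrial transcripts (MT-CO3 -0.98 ± 0.09, list adjusted p = 1.25e-09, and adjusted p = 0.149 with an estimated correlation). They were also called for 18 of 29 interferon genes, with 3 higher (IFIT1 -1.79 ± 0.17, adjusted p = 7.96e-06, and adjusted p = 0.119 with an estimated correlation). FOXO targets (11 of 19, adjusted p = 0.000308, and adjusted p = 0.149 with an estimated correlation), mesenchymal genes (10 of 17, with 3 higher, 0.000957 and 0.149) and hypoxia targets (6 of 13, 0.0182 and 0.244) were also lower. PIK3IP1 differed by -1.78 ± 0.26 and COL5A1 by -1.29 ± 0.12. Lysosome genes were lower in 8 and higher in 2 of 26 cases (adjusted p = 0.0385, and adjusted p = 0.399 with an estimated correlation). This call was lost without LC-2/ad parent library 2 (0.0527), LC-2/ad treated library 1 (0.0505) or TPC-1 treated library 3 (0.0587), without the filter (0.0802) and without a variance trend (0.0551). ERBB2 differed by -0.81 ± 0.07, RET by -0.43 ± 0.10 and MET by 0.91 ± 0.11. ERBB3 differed by -0.51 ± 0.18 (adjusted p = 0.0407), a call that ended in 8 of the 12 fits that leave out 1 library, with an adjusted p of up to 0.1 (without LC-2/ad parent library 2). YAP/TAZ targets were not called as a list (5 higher and 7 lower of 21, adjusted p = 0.246), and neither were antigen presentation genes (0 and 2 of 10, 0.0552, but 0.0371 and 0.0485 without TPC-1 parent and treated library 2, 0.0277 with a pseudocount of 5 and 0.0262 at a mean TPM of at least 5). Nor were BCL2 family (4 and 3 of 13, 0.428), receptor tyrosine kinases (7 and 6 of 18, 0.588), epithelial genes (5 and 1 of 14, 0.605) or CDK inhibitors (4 and 4 of 15, 0.611). Lists of p53 targets (8 and 3 of 21, 0.68), lung lineage genes (2 and 2 of 6, 0.96) and growth factor ligands (4 and 3 of 13, 0.962) were not called. Single differences among the largest were those of the tubulin gene TUBA1A (-2.34 ± 0.14) and the histone gene H2AC6 (-2.37 ± 0.21), both with near-identical copies in the genome and so uncertain, and of CDKN1C (-2.33 ± 0.48). The pseudogene BRCA1P1 was at 2.89, 2.69 and 7.81 TPM in TPC-1 parent libraries and listed at 0 in the treated ones. In LC-2/ad it was at 24.8, 3.06 and 0 TPM in parent and at 15.9, 25.5 and 11.5 TPM in treated libraries.

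Genes that rose in both lines by the most included IGFBP5 (2.75 in LC-2/ad and 1.55 in TPC-1 on the log2 scale), IL32 (1.49 and 1.28), EDN1 (1.24 and 1.58), FILIP1L (1.38 and 1.22) and EDN2 (1.08 and 2.96). Genes that fell in both included EGR1 (-1.41 and -1.31), ETV4 (-2.94 and -1.19), HES1, a Notch target (-1.31 and -1.13), SPRY4 (-1.47 and -1.08) and TMEM156 (-1.38 and -1.16). The TPC-1 fall of TMEM156 had an adjusted p of 0.0584 without TPC-1 treated library 1 and 0.0612 without the filter. In TPC-1 SPRY4 fell from 2.55 to 0.702 TPM, HES1 fell from 3.22 to 0.934 TPM, and EDN1 rose from 1.2 to 5.61 TPM. At such low levels the added 1 shrinks a log2 fold change, so sizes cannot be ranked between the lines for these genes. The difference of EDN1 was called with a pseudocount of 0.1 (0.79, limma adjusted p = 0.00903). Those of SPRY4 (0.65) and HES1 (0.642) were called with a pseudocount of 5. Of 11996 genes tested in both lines 230 rose in both and 74 fell in both, 304 together, where independent lists would share 123.2 and 36. Another 24 rose in LC-2/ad and fell in TPC-1 (38.4 for independent lists), and 64 did the reverse (115.8). Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.204 and a Spearman rho of 0.216.

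By limma the response differed in 4393 of 11996 genes (36.6%), with a higher TPC-1 log2 fold change in 2660 and a lower one in 1733. Camera called 18 of 27 lists, 12 higher and 6 lower, and with an estimated correlation 3 calls held: S phase (adjusted p = 0.00182), G2/M (0.0282) and nuclear respiratory chain (0.0282). Direction among single genes depended on scaling, with 2066 higher and 2302 lower after removal of mitochondrial genes. The 304 shared changes became 134 without the filter on low values and 170 without a variance trend, and 162, 144, 164 and 167 without TPC-1 parent libraries 2 and 3 and treated libraries 1 and 2.

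**Figure D3:**
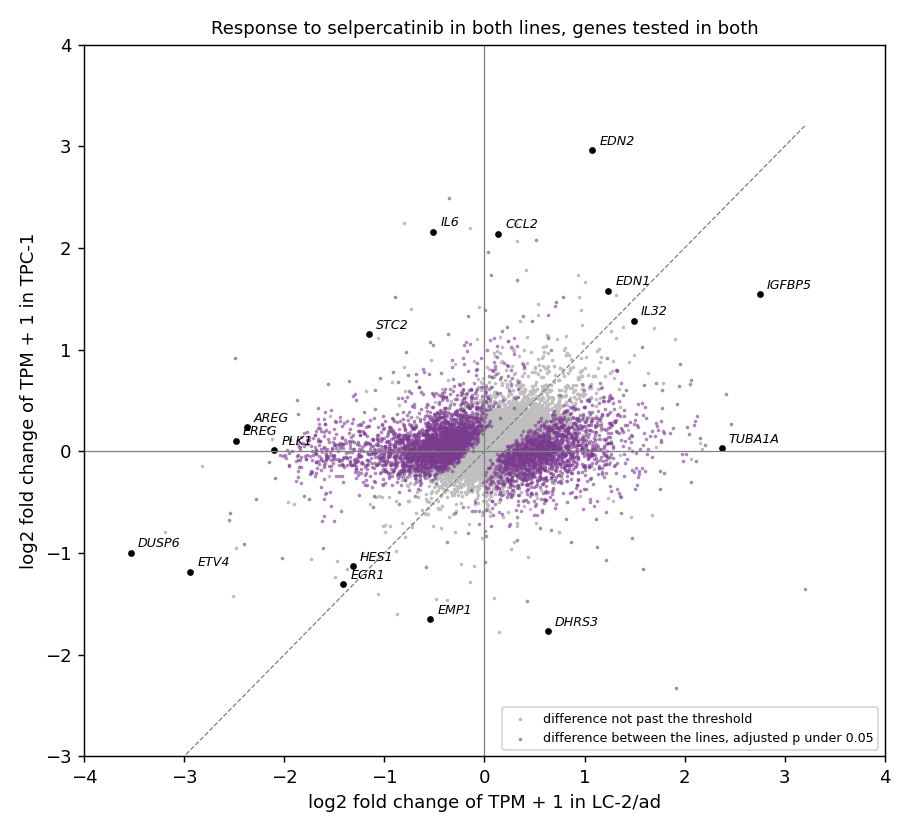
Log2 fold changes of TPM + 1 in LC-2/ad (horizontal axis) and TPC-1 (vertical axis) for the 11996 genes tested in both lines, n = 3 libraries per group, with 1 point, SRP9P1, outside the axes. Purple points are the 4393 genes whose response differed between the lines at an adjusted p under 0.05, the dashed line marks equal change, and the points spread further along the LC-2/ad axis than along the TPC-1 axis (Pearson r 0.204).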

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

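The tests of the pseudocount, of blood cell RNA, of single TPC-1 libraries and of the mitochondrial share were chosen after the results were seen. The results of this part are listed because the response to selpercatinib differed between LC-2/ad and TPC-1 by a test of the difference itself, in 4393 genes and 18 gene lists. With an estimated correlation 3 of these lists were called.

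TPC-1 had fewer changed genes than LC-2/ad (636 against 7770) and a smaller fall of the ERK feedback list (adjusted p of the difference = 0.00017, and adjusted p = 0.155 with an estimated correlation). A larger spread between TPC-1 libraries is argued against as the whole cause, since the LC-2/ad group means with the TPC-1 residuals gave 5606 calls, against 556 for TPC-1 itself in the same 11996 genes. With 1 library left out that was 6.68 to 17.54 times as many calls. For the ERK feedback list, low TPC-1 levels squeezed by the pseudocount are argued against by a median difference of 0.69 at a pseudocount of 0.1 (0.67 at 1, and 0.55 to 0.78 with 1 library left out). The drug's solvent, the state of the cultures and the biological difference between a lung and a thyroid line stay open and were not tested.

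Inflammatory genes rose in TPC-1 in 11 of 16 cases, and 9 of 14 had a higher log2 fold change than in LC-2/ad (1 a lower one). Both list calls ended with an estimated correlation (adjusted p = 0.317 with an estimated correlation in TPC-1 and 0.214 for the difference). RNA from blood cells is argued against by the blood cell markers PTPRC, CD14, LYZ and TYROBP, of which the highest, CD14, had a mean of 0.131 TPM in treated TPC-1 cells, where CCL2 alone had 62.3 TPM. A single TPC-1 library is argued against as well, since the list median of 1.11 was at least 0.96 over the fits that leave out 1 library, with 6 to 13 members rising. A response of the TPC-1 cells to the drug or to their culture conditions stays open, and no biological explanation was tested.

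In LC-2/ad the mitochondrial share rose to 14.01% to 14.95% in the treated libraries while nuclear respiratory chain genes fell. A larger mitochondrial share lowers all other TPM, but with the mitochondrial genes removed the list median was still -0.21 (15 members lower). After median-of-ratios scaling it was -0.35, against -0.29 as deposited. The camera adjusted p with these genes removed (6.37e-06) cannot weigh this. Camera compares the list with other genes, and a rescaling moves them nearly alike. The share therefore does not account for the whole fall of that list. RNA quality and the handling of treated cultures stay open as sources of the mitochondrial rise itself and were not tested, since no measure of RNA integrity was had.

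For 6 libraries of 1 line there are 10 splits into 3 and 3, too few for a share under 0.05. The real split was the highest 1 of 10 for changed genes, with 7770 in LC-2/ad (highest other 0) and 636 in TPC-1 (highest other 2). It was also the highest for called lists, with 19 in LC-2/ad (highest other 17) and 10 in TPC-1 (highest other 8). The number of called lists was thus close to what another split gives. But each other split sets 2 libraries of 1 treatment with 1 of the other, so part of the response can stay in it. These splits therefore cannot say how many lists chance would give. Splits within both lines were drawn 100 times. For the genes whose response differed 2 of 100 splits gave as many as 4393, a share under 0.05. The other gave 5573, from the split that keeps the LC-2/ad groups and exchanges the TPC-1 ones. Splits that mix the LC-2/ad groups dilute the response of that line itself, and the rest of it adds to the spread within the mixed groups. The share therefore cannot exclude chance for a difference between the lines. For the 304 shared changes 1 of 100 splits gave as many (highest other 88). But other splits of a line called 0 genes in LC-2/ad and at most 2 in TPC-1, so they could share almost none. This test therefore cannot say whether the overlap exceeds chance. For the correlation of 0.204, 4 of 100 splits gave a size as large (highest other 0.205), a share under 0.05. But the 3 drawn splits that keep the TPC-1 groups and mix the LC-2/ad ones gave 0.205, 0.196 and -0.166, so 1 of them reached its size. In these the LC-2/ad groups still hold part of that line's response, and a correlation does not depend on the size of that part. These splits therefore cannot say whether the correlation exceeds chance. For the 18 lists whose response differed 2 of 100 splits gave as many (highest other 18, with the TPC-1 groups exchanged), also a share under 0.05. A split that mixes both lines gave 16, so this number of lists too was close to what another split gives, with the same limit. The 7 drawn splits that keep the LC-2/ad groups and mix the TPC-1 ones gave 3616 to 4053 genes and 16 to 17 lists whose response differed, so these 2 counts rest mostly on the LC-2/ad groups. For the TPC-1 groups alone there are too few splits.

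Of the 18 lists S phase, G2/M and nuclear respiratory chain genes were called with an estimated correlation and the other 15 were not. The list medians of the difference in log2 fold change (TPC-1 minus LC-2/ad) were 1.69 for G2/M, 1.46 for S phase, 0.73 for inflammatory cytokines, 0.68 for fatty acid synthesis, 0.67 for ERK feedback, 0.65 for ribosome biogenesis, and 0.58 for the ATF4 response. They were 0.51 for glycolysis, 0.48 for heat shock, 0.47 for cholesterol synthesis, 0.27 for nuclear respiratory chain genes and 0.22 for the unfolded protein response. They were -0.77 for interferon response, -0.73 for mitochondrial transcripts, -0.55 for mesenchymal genes, -0.47 for FOXO targets, -0.42 for hypoxia and -0.16 for lysosome and autophagy.

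Of 118 named genes tested, 94 had a called difference, against 36.6% of all 11996 genes tested. Many were named for the size of their change or difference, so the larger share follows in part from that choice. SRP9P1, RPL39P16, BRCA1P1 and RPP21, with values of 0 in treated libraries and, except for RPP21, also in some parent libraries, are not counted. Of these SRP9P1 (adjusted p = 0.00262) and BRCA1P1 (adjusted p = 0.0129) passed the test of the difference, and no size is given against groups listed at 0. For cell cycle genes the difference was CDC6 1.73, DLGAP5 1.82, MKI67 1.69, PLK1 2.11, RRM2 2.00 and TK1 1.77. The others were TOP2A 1.92, CCND1 0.78, CDKN2C 0.99, CDKN2D 1.37 and CDKN1C -2.33. For ERK and growth factor signalling it was DUSP6 2.54, ETV4 1.75, ETV5 1.87, MYC 0.59, AREG 2.61 and EREG 2.59. For receptors and other ligands it was EGFR 0.40, MET 0.91, RET -0.43, ERBB2 -0.81, ERBB3 -0.51, GAS6 -0.88, IGFBP3 1.01, IGFBP5 -1.20, TGFB2 -1.05 and CCN2 -0.67. For NF-kB and immune genes it was IL6 2.67, CCL2 2.01, TRAF1 1.57, TNFRSF9 1.36, BIRC3 0.76, NFKBIA 0.73, NFKBIE 0.73, NFKB1 0.56, NFKB2 0.48, RELB 0.94, MAP3K14 0.82. For other immune genes it was APOBEC3B 1.94, IFI27 -2.13, IFIT1 -1.79, IRF9 -1.47, HLA-E -0.90 and TNFSF10 -1.23. For metabolism, stress and mitochondria it was SCD 1.48, FADS2 1.61, INSIG1 1.32, LDHA 1.11, PFKP 0.29, STC2 2.31, GDF15 1.93, HSPB1 0.48, HSPD1 0.77, HSPH1 1.18, HYOU1 0.46, XBP1 0.22, HERPUD1 -0.44. Others were ADM -0.60, NOP56 1.07, ODC1 0.60, CYCS 0.96, SDHB 0.44, MT-CO3 -0.98, MT-ND1 -0.81, NQO1 0.17. For enzymes, transport, autophagy and cell death it was CYP1B1 -1.42, UGT1A6 -0.53, DHRS3 -2.40, SLCO4A1 0.98, PIK3IP1 -1.78, GABARAPL1 -0.53, WIPI1 -0.99, TP53INP1 -2.04, BMF -1.03 and BCL2L11 -0.80. For structural, lineage and other genes it was ACTA2 -0.69, AQP3 0.86, CLIC3 -2.20, COL5A1 -1.29, EDN2 1.88, ELF3 0.44, EMP1 -1.11, FOXE1 -1.53, KRT18 0.25. Further ones were SOX9 -1.10, TGM2 -0.55, TMEM40 1.92, TNC 0.82, TUBA1A -2.34, TUBA1B 1.14, H1-2 -1.33, H2AC6 -2.37, H2BC5 -1.14 and H3C10 0.69. Calls under the alternatives were followed gene by gene only for genes named by the rule. They were not followed for NQO1, CYP1B1, UGT1A6, RELB, NFKB1, NFKB2, NFKBIE, MAP3K14, APOBEC3B, TUBA1B, H1-2, H2BC5 and H3C10. Among those followed, some calls ended under an alternative. The highest adjusted p over the alternatives was 0.103 for GABARAPL1 (without LC-2/ad parent library 2), 0.1 for ERBB3 (the same), 0.0726 for HERPUD1 (without LC-2/ad parent library 3), 0.132 for PFKP and 0.192 for XBP1 (both with the mitochondrial genes removed). These 5 calls also ended in 7 or more of the 12 fits that leave out 1 library. The difference of BIRC3 was 0.18 with a pseudocount of 5 (adjusted p = 0.181), and the call of KRT18 ended after median-of-ratios scaling (0.0508) and with the mitochondrial genes removed (0.0791).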

How the results depend on the processing

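Protein-coding genes alone and a spread weight per line were chosen after seeing the data. Counts of changed genes in LC-2/ad and of genes whose response differed stayed within 1.5 times the values reported under every alternative run, as did the counts of called lists under other gene-level settings. The exception was a minimum change of 1 on the log2 scale, which left 1115 genes in LC-2/ad and 79 in TPC-1. No gene named by the rule reversed its sign of a called change, and other genes were not followed 1 by 1. In TPC-1 the 636 genes became 272 without the filter, where more genes were tested, and 356 without a variance trend, and ranged from 292 to 815 when 1 library was left out. Shared changes (304) became 134 and 170 under these settings and ranged from 144 to 404. The correlation of 0.204 was 0.172 with a pseudocount of 0.1, 0.216 with 5, 0.15 without the filter, 0.23 at a mean TPM of at least 5 and 0.227 with protein-coding genes alone, and ranged from 0.18 to 0.211 when 1 library was left out. With an estimated correlation 7 lists were called in LC-2/ad, 0 in TPC-1 and 3 for the difference, and fry called 26, 2 and 20. The growth factor ligand list reversed its direction under fry in LC-2/ad (median log2 fold change 0.212) and for the difference (-0.139). Median and mean differed in sign for that list, CDK inhibitors and the unfolded protein response in LC-2/ad. They also did for CDK inhibitors and FOXO targets in TPC-1. Camera gave no call in these cases, but in LC-2/ad fry called the ligand list (fry adjusted p = 0.000147) and CDK inhibitors (fry adjusted p = 0.0178). The ribosome list in TPC-1 had a positive median and mean and a negative direction by camera. Camera compares a list with all other tested genes. The ribosome list mean of 0.003 lay below the median of 0.048 over all tested TPC-1 genes. The cause of the other shifts was not tested. With the replicate number as a block the counts were 7357, 542, 4227 and 253 shared. Parent and treated libraries of the same number had correlations of -0.04, -0.015 and -0.048 in LC-2/ad and 0.054, -0.026 and 0.039 in TPC-1. Pairs of unlike numbers ranged from 0.003 to 0.04 in LC-2/ad and from -0.116 to 0.087 in TPC-1. With 3 libraries per group this is a weak check that cannot exclude pairs, and the numbers were not read as pairs. Leaving out 1 library gave 6888 to 7226 genes in LC-2/ad, 3895 to 4273 differences, and 19 to 20, 7 to 11 and 16 to 19 called lists. The spread weight per line gave 4386 genes and 18 lists. Depth limits are unknown, since TPM hold no counts.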

Other observations

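All genes of this part lie outside the naming rule or were looked at after their values were seen, and so was the test of the hypothesis below. Histone genes of the clustered, replication-dependent class, chosen by symbol, give transcripts that are made mostly in S phase and mostly lack a poly(A) tail. Of 27 such genes tested in LC-2/ad, where all S phase genes of the list fell, 13 rose, 2 fell and 12 did not pass the limma test, and no list test was run on them. They had a median log2 fold change of 0.54. H2BC5 rose from 14.4 ± 1.14 to 34.8 ± 1.04 TPM (mean ± SD, n = 3) and H1-2 from 12.2 ± 3.71 to 28.6 ± 3.21 TPM, while H3C10 fell by 0.51 ± 0.16 (SE). In TPC-1 limma called 0 of 29 histone genes, with 2 at an unadjusted p under 0.05 and a median of 0.01. Histone genes have near-identical copies, so single values are uncertain. The tubulin genes TUBA1A and TUBA1B, also near-identical, moved apart in LC-2/ad (2.37 ± 0.07 and -1.16 ± 0.03), and KRT17, a keratin of basal epithelial cells, rose from 9.88 ± 1.65 to 57.3 ± 2.96 TPM.

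Of the 5 genes for NF-kB proteins 3 rose in TPC-1 and 3 in LC-2/ad. RELB rose from 6.44 ± 0.379 to 17.7 ± 0.671 TPM, a log2 fold change of 1.33 ± 0.09. NFKB2 rose by 1.11 ± 0.07, NFKB1 by 0.61 ± 0.09, the kinase gene MAP3K14 by 1.12 ± 0.18 and the inhibitor gene NFKBIE by 0.80 ± 0.11. RELA (-0.0037 ± 0.06, adjusted p = 0.985) and REL (0.16 ± 0.16, adjusted p = 0.628) did not pass. TNFAIP3, another NF-kB inhibitor, had a log2 fold change of 0.59 ± 0.20 and an adjusted p of 0.132. In LC-2/ad RELB rose by 0.39 ± 0.06, NFKB2 by 0.64 ± 0.08, REL by 0.54 ± 0.11 (adjusted p = 0.00422), MAP3K14 by 0.30 ± 0.06 and TNFAIP3 by 0.36 ± 0.09 (adjusted p = 0.0133). NFKB1 (adjusted p = 0.686), RELA (0.0661) and NFKBIE (0.506) did not pass there. The difference between the lines was 0.94 for RELB (adjusted p = 1.51e-05) and 0.48 for NFKB2 (adjusted p = 0.00543). GFRA1, a coreceptor of RET for its ligand GDNF, rose in TPC-1 from 217 ± 2.44 to 334 ± 16.2 TPM and was too low to test in LC-2/ad. The cytidine deaminase gene APOBEC3B fell in LC-2/ad from 71.2 ± 3.0 to 23.9 ± 1.18 TPM and rose in TPC-1 from 27.8 ± 0.253 to 37.1 ± 0.815 TPM, a difference of 1.94 (adjusted p = 1.14e-08), with the reservation on shared reads given for its paralog.

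A hypothesis for the rise of CYP1A1 in LC-2/ad is activation of the aryl hydrocarbon receptor, which induces a known set of xenobiotic enzymes. Of 8 such genes 5 rose, CYP1A1 (3.40 ± 0.05), CYP1A2 (2.15 ± 0.13), CYP1B1 (1.59 ± 0.06), AHRR (1.04 ± 0.26) and UGT1A6 (1.32 ± 0.10), but NQO1 (-0.49 ± 0.04) and ALDH3A1 (-1.0 ± 0.15) fell and TIPARP (-0.07 ± 0.06, adjusted p = 0.286) did not pass. The receptor gene AHR rose by 0.42 ± 0.07. UGT1A6 shares exons with other genes of its locus, so its value is uncertain. CYP1A1 prompted the hypothesis, so its own rise is no support for it, and 4319 of all 14118 tested LC-2/ad genes rose. With the other genes going both ways, activation of the receptor cannot be told apart from other routes to these genes.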
